A study of Mus musculus with 10 samples.

How the data were processed

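Spermatogonia with an ID4-EGFP reporter were taken from testes of mouse pups at postnatal day 6 and sorted by TSPAN8 staining, the most strongly stained cells as TSPAN8-high and the most weakly stained as TSPAN8-low. Per the labels, DNA from 5 pooled sorts (300 ng) of each fraction was sequenced by RRBS with paired reads of 50 bp, which gave 1 library per fraction. The series has 10 samples, and the 8 chromatin samples, from 8 pooled sorts, were not analysed here.

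The authors deposited 1 table in which each line is a cytosine of a CpG on 1 strand. The deposited methylation level is a fraction, methylated reads over all reads, rounded to 2 decimals. The deposited coverage columns hold read counts, with no value below 5 in either library. The deposited difference column (unit other) holds the level of TSPAN8-high minus that of TSPAN8-low, as a fraction. The deposited p-value equalled the two-sided p of Fisher's exact test on the read counts, within a relative tolerance of 0.001, at 93.6% of cytosines in the authors' deposited table. The submitters' processing notes name mm9, mm10, Bowtie and SICER without saying for which assay. Positions on the Y chromosome and the place of the drop in methylation at annotated gene ends were checked against the gene table, and mm10 coordinates were used.

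Methylated reads were computed as level times coverage, rounded. Cytosines with at least 10 reads in both libraries were kept, which left a median of 16 reads per cytosine in each. Levels were averaged over cytosines, with a jackknife over blocks of 1 Mb, and also weighted by reads. Cytosines were split into those within 1 kb of an end of a protein-coding gene, gene bodies and intergenic, and by the number of listed CpGs in 200 bp. The gene table gave neither strands nor exons, so the planned classes of exon and intron and the annotated transcript start were replaced: the promoter was taken as the end of each gene with more listed CpGs. Of 2036 genes with both ends measured, that end was the less methylated at 79.1%, and 10849 genes had 1 end measured.

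Libraries were compared by two-sided Fisher's exact tests on methylated and unmethylated reads, adjusted by the Benjamini-Hochberg method over all features of a kind. Single cytosines were called at an adjusted p below 0.05 and a difference of at least 20 percentage points. Tiles of 1 kb with at least 3 CpGs and promoter windows of 1 kb either side with at least 5 CpGs were called at a difference of at least 10 percentage points, with reads pooled over CpGs. A read that covers several CpGs is counted at each, which makes these p values too small. Read numbers were even at 73.0% of cytosines in TSPAN8-high and 73.1% in TSPAN8-low. Intervals of differences in pooled reads are Newcombe intervals, and intervals of single levels are exact Clopper-Pearson intervals. Intervals of averaged levels come from the jackknife. Those over bins of 100 bp or over called CpGs rest on the standard error across them. Sequencing reads without molecular identifiers are not independent molecules. Newcombe and exact intervals, and the 3 counts that a share of 0 allows, therefore cover counting error only. The other intervals cover spread along the genome, and none covers error between replicates. On simulated data with changes of 20 and 40 percentage points, the promoter test called 99% and 100%, the tile test 40% and 92%, and the test of single cytosines 0 at either size. Depth and the number of cytosines adjusted over were not separated in this simulation. Its reads were drawn independently, so these shares do not hold for reads that are counted at several CpGs.

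Tspan8, Id4 and the imprinted regions were always named. The further named genes are the 10 with the largest rise and the 10 with the largest fall in promoter methylation among called protein-coding genes whose symbol is not a placeholder, and the 5 tiles with the largest rise and the 5 with the largest fall. From each list up to 4 called members were named, or, with fewer than 2 called, the 2 members with the most reads. The 15 lists are stem cell and self-renewal, differentiating spermatogonia, meiosis, spermiogenesis, germline genes repressed by DNA methylation in somatic cells, pluripotency, Hox clusters, DNA methylation and demethylation enzymes, TGF-beta, BMP and ID genes, tetraspanins, Sertoli cells, Leydig cells, peritubular myoid cells, endothelial cells, and macrophages and leukocytes. The median promoter difference of a list was set among 10000 random lists matched on methylation. Imprinted windows were counted with at least 5 CpGs, the minimum for promoters, which the plan did not name for them, and their Fisher's exact tests were added after the plan. They lay 1 kb either side of a gene end, or upstream by 1 to 5 kb for H19, 10 to 16 kb for Meg3 and 25 to 35 kb for Rasgrf1.

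Alternatives chosen before the data were examined were at least 5 or 20 reads, read-weighted means, no minimum difference or a higher one, no sites above the 99.9th percentile of coverage, equal coverage in both libraries, 1 CpG per 100 bp, promoter windows of 500 bp or 2 kb either side, and an unweighted mean over CpGs. Alternatives chosen after seeing the data were counts halved where all were even, merged strands, the less methylated gene end and the same imprinted windows at each minimum of reads. As a check for noise confined to a strand, the libraries were exchanged on the minus strand. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Numba 0.67.0 and Matplotlib 3.10.9.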

Results

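DNA methylation was measured by reduced-representation bisulfite sequencing (RRBS), which samples CpG-rich restriction fragments, in spermatogonia of mouse pups at postnatal day 6. The cells expressed an ID4-EGFP reporter, which marks spermatogonia with stem cell potential, and were sorted by antibody staining for the surface tetraspanin TSPAN8 into a TSPAN8-high and a TSPAN8-low fraction. Each fraction gave 1 library, made from 5 pooled sorts, so there were no replicates and no error between replicates could be given. The other 8 samples of the series, chromatin immunoprecipitation and input libraries, were not analysed here. The deposited table held 6745376 cytosines in 4489220 CpGs, with 83658949 reads over these cytosines in TSPAN8-high and 83773700 in TSPAN8-low, and a median of 10 reads per cytosine in each. At least 10 reads in both libraries were found at 2691781 cytosines in 1895357 CpGs, where the median was 16 reads in each. Intervals cover counting error or spread along the genome, not error between replicates. Tests compare the 2 libraries, not the conditions.

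The first comparison asked whether the sorted fractions, expected to differ in stem cell content, differed in overall methylation and in which parts of the genome. Both methylomes were methylated outside CpG-dense regions and differed by little. Intergenic cytosines averaged 81.5% in TSPAN8-high and 81.7% in TSPAN8-low, and gene bodies 82.1% and 82.2%. Within 1 kb of the ends of protein-coding genes, 368870 cytosines averaged 15.2% in both libraries, with a difference, high minus low, of 0.0128 percentage points (95% jackknife interval -0.0133 to 0.0389). Sites with 10 or more listed CpGs in the surrounding 200 bp averaged 1.58% in both libraries. Sites with at most 2 listed CpGs averaged 89.5% in TSPAN8-high and 89.7% in TSPAN8-low, and sites with 3 to 9 averaged 64.8% and 64.9%. Over all cytosines the mean level was 72.7% in TSPAN8-high and 72.8% in TSPAN8-low, a difference of -0.108 percentage points (jackknife standard error 0.00785 over 2651 blocks of 1 Mb). Weighted by reads, the levels were 70.8% and 71.4%, a difference of -0.578 percentage points. At 20 or more reads the weighted difference was 0.0345 (95% Newcombe interval 0.000512 to 0.0686). Levels below 20% were found at 21.3% of cytosines in TSPAN8-high and 21.4% in TSPAN8-low, and levels above 80% at 69.0% and 69.3%. The autosomes differed by -0.107 percentage points and the X chromosome, at 73.7% and 73.8%, by -0.067 (95% jackknife interval -0.262 to 0.128). The Y chromosome, with 1137 cytosines, averaged 57.9% in TSPAN8-high and 59.5% in TSPAN8-low, a difference of -1.55 percentage points (95% jackknife interval -2.51 to -0.595), which was -1.18 at 5 or more reads and -0.899 at 20 or more (95% jackknife interval -1.98 to 0.178). In the profile around the CpG-richer end of each gene, methylation dropped to 1.75% in TSPAN8-high and 1.77% in TSPAN8-low, and the libraries differed by at most 1.53 percentage points in any bin.

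**Figure D1:**
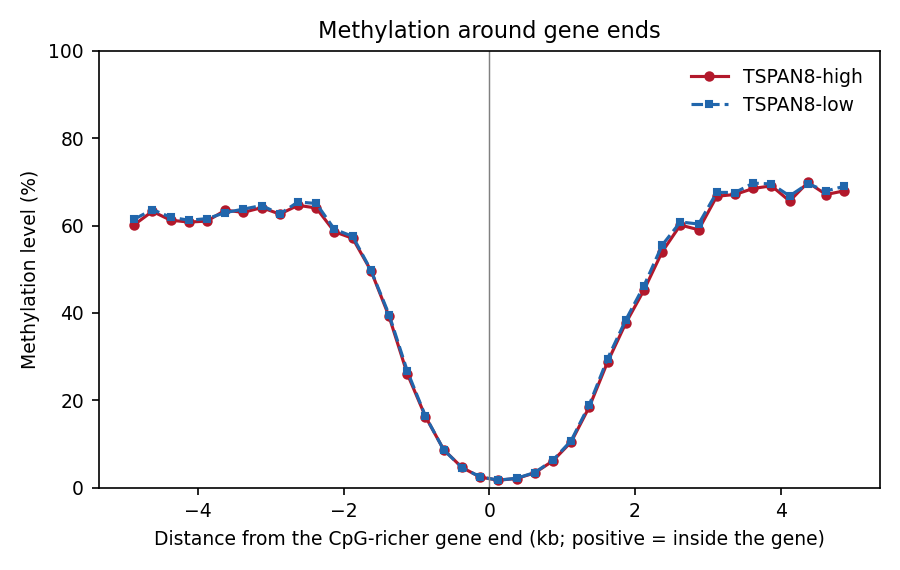
Methylation level (percent) in bins of 250 bp within 5 kb of the CpG-richer end of protein-coding genes, with 1 line for each library; positive distances (kb) lie inside the gene. The lowest bins are at 1.75% in TSPAN8-high and 1.77% in TSPAN8-low.

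The second comparison asked at which places outside and inside genes the fractions differed, by Fisher's exact test at single cytosines and in 1-kb tiles. Among tiles higher in TSPAN8-high, the largest differences lay at Bcam, which encodes a laminin-binding adhesion molecule (68.2% against 9.09%, chromosome 7, 19756001 to 19757000), and inside Aass, a gene of lysine breakdown (66.7% against 10%, chromosome 6, 23085001 to 23086000). Next came a tile within 1 kb of an end of the RNA gene Gm32339 on chromosome 18 (73.3% against 17.4%), a tile 7608 bp from the ribosomal protein gene Rpl11 on chromosome 4 (90% against 37.1%) and a tile 5225 bp from the cell polarity gene Crb2 on chromosome 2 (71.7% against 20%). Lower in TSPAN8-high were tiles 41637 bp from Gm26901 on chromosome 1 (38.7% against 100%) and 3046 bp from Gm31854 on chromosome 18 (33.3% against 94.4%). So were a tile 39629 bp from the apolipoprotein gene Apob on chromosome 12 (36.1% against 93.3%), one inside Gm25136 on chromosome 6 (42.9% against 100%) and one at Gm41686 on chromosome 18 (22.2% against 77.8%). Each of these 10 tiles held 3 CpGs. Of 187549 tiles with at least 3 CpGs, 644 were called higher and 572 lower in TSPAN8-high, at an adjusted p below 0.05 and a difference of at least 10 percentage points. Of intergenic tiles 0.895% were called, of gene body tiles 0.530% and of tiles within 1 kb of a gene end 0.265%. Among tiles with a mean level from 10% to 90%, which made up 23.3%, 11.1% and 10.9% of these places, the shares called were 2.89%, 2.99% and 1.86%, and they were not tested against each other. Of 2691781 single cytosines, 97 were called higher and 56 lower by at least 20 percentage points, while with no minimum difference 98 were higher and 186 lower. With 1 CpG kept per 100 bp, 65 tiles were called, and 44 of the 1216 tiles called before were among them in the same direction. Of the 10 named tiles, those of Aass, Rpl11, Gm31854 and Gm25136 kept their call. Among those that lost it, the difference fell to -20 percentage points at Apob. It stayed large at Bcam (49.2), Gm32339 (67.5), Crb2 (45.4), Gm26901 (-45.5) and Gm41686 (-50). The thinned reads are part of the reads by which the 10 tiles were picked, so kept sizes and calls are no independent support. With all CpGs kept, the libraries were also exchanged on the minus strand. This cancels a difference that both strands share only where their read numbers are equal. After the exchange 474 tiles were called, against 588 in the real comparison of the same 56136 tiles.

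**Figure D2:**
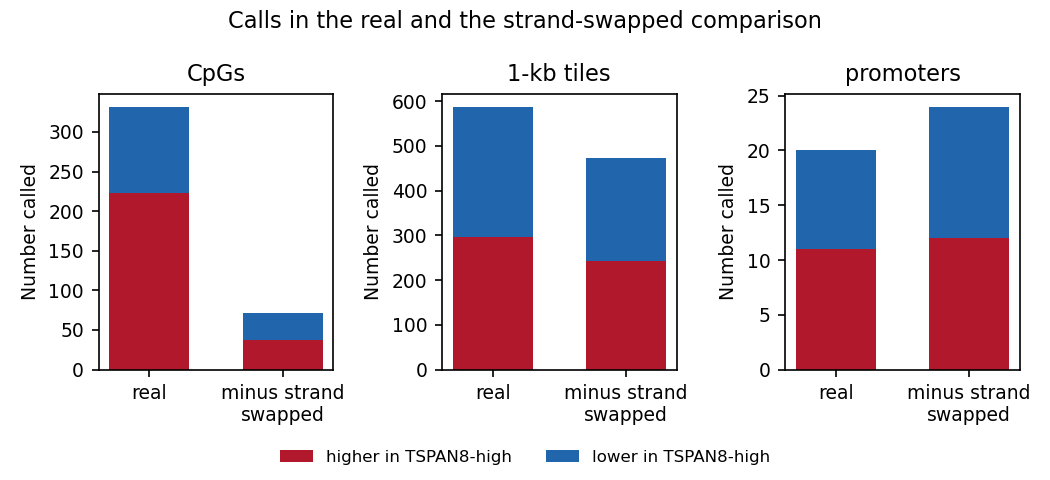
Number of CpGs, 1-kb tiles and promoters called higher or lower in TSPAN8-high, among CpGs measured on both strands, in the real comparison and with the libraries exchanged on the minus strand. The real comparison called 332 CpGs, 588 tiles and 20 promoters, and the exchanged one 72, 474 and 24.

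The third comparison asked which promoters differed between the fractions. Promoter windows reached 1 kb either side of the CpG-richer end of each gene, since the gene table gave no strand, so which end of a gene a window covers cannot be told for certain. The windows with the largest higher levels in TSPAN8-high were those of the cytochrome P450 gene Cyp4a29 (58.6% against 26.6%), of Trafd1, a regulator of innate immune signalling (50% against 28.7%), and of Ctc1, a component of the telomere replication complex CST (58.4% against 37.5%). The zinc finger genes Zscan26 (38.2% against 17.7%) and Zfp141 (20.2% against 0 of 73 reads, which allows up to 4.11%) followed. Olfm4, a secreted glycoprotein of the gut epithelium, had 50.4% against 30.1%, and Pigu, a subunit of the enzyme that attaches lipid anchors to proteins, 76.6% against 56.9%. Rxfp2, the receptor of the testis hormone INSL3, had 20% against 1.67%, the immune receptor gene Cd40 had 57.9% against 39.6%, and the notochord homeobox gene Noto had 59.1% against 41.0%. Lower in TSPAN8-high were the windows of the myosin gene Myo1h (5.04% against 24.6%), of Tnfsf4, which encodes OX40 ligand (35.4% against 54.8%), of the clustered protocadherin gene Pcdhb3 (13.7% against 31.9%) and of Pgr, the progesterone receptor (29.3% against 47.4%). Schip1 had 41.5% against 57.9%, Elmod3 and the retinol saturase gene Retsat, which share a window, 25.1% against 41.4%, and the RNA helicase gene Ddx47 14.8% against 31.0%. Sdr42e1, a short-chain dehydrogenase, had 15.8% against 31.9%, and Rangrf, a gene of nuclear transport, 20.6% against 36.5%. Among these genes, none with a placeholder symbol, the largest differences were -19.6 percentage points at Myo1h (95% interval -28.2 to -10.9, adjusted p = 0.00316, Fisher's exact test) and 32.0 at Cyp4a29 (95% interval 16.2 to 45.7, adjusted p = 0.0117, Fisher's exact test). The lowest adjusted p among these genes was that of Ctc1 (0.000395, Fisher's exact test, with 262 reads in TSPAN8-high and 344 in TSPAN8-low), but the other end of Ctc1, with 6 CpGs, was unmethylated in both libraries (0 of 170 and 0 of 131 reads, which allows up to 1.76% and 2.29%), so which end of Ctc1 is its promoter is open.

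In all, 12885 of 21887 protein-coding genes had a window with at least 5 CpGs, of which 22 were called higher and 26 lower in TSPAN8-high by at least 10 percentage points, and 399 had an adjusted p below 0.05 at any size of difference. Most promoters were unmethylated in both fractions, with 90% below 20% and 4.29% above 80% in both libraries, and the middle 95% of differences ran from -5.48 to 5.23 percentage points. Levels correlated across promoters with a Pearson r of 0.992, though genes are not independent replicates. Of the 48 called windows, 44 had a mean level between 5% and 70%, a range that held 16.4% of the windows tested. A window with a mean level below 5% cannot reach a difference of 10 percentage points. The threshold therefore fixes part of this contrast. With 1 CpG kept per 100 bp no promoter was called: all 20 named promoters kept their direction, 5 with a larger and 15 with a smaller difference, and 10 with a 95% interval that left out 0, while their median reads in both libraries together fell from 353.5 to 161.5. At Cyp4a29 the difference was then 38.8 percentage points (95% interval 15.8 to 56.9) and at Pgr -5.81 (95% interval -20.7 to 9.29). The thinned reads are part of the reads by which these promoters were picked. Their kept directions and intervals are therefore no independent support. With the libraries exchanged on the minus strand 24 promoters were called, against 20 in the real comparison of the same windows. At 5 or more reads 5 of the 20 named promoters lost their call: Zscan26 (9.82 percentage points), Pigu (7.85), Myo1h (-1.45), Tnfsf4 (-11.5) and Pcdhb3 (-8.75). Taking windows of 2 kb either side turned the direction at Cyp4a29, Rxfp2, Myo1h and Rangrf, and the unweighted mean of the CpGs turned it at Ctc1, Pigu, Schip1 and Ddx47.

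**Figure D3:**
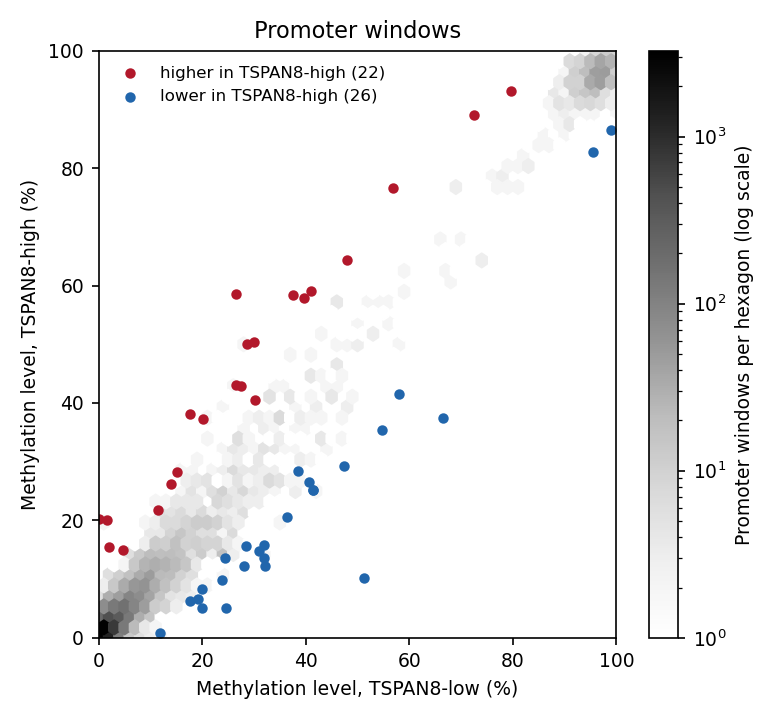
Methylation level (percent) of 12885 promoter windows in TSPAN8-low (horizontal) and TSPAN8-high (vertical), shaded by the number of windows per hexagon on a log scale. Red points are the 22 windows called higher and blue points the 26 called lower in TSPAN8-high.

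The fourth comparison asked whether methylation differed at the genes that define the fractions. Tspan8, the tetraspanin used for sorting (chromosome 10, 115816817 to 115849893), had no cytosine with at least 10 reads within 1 kb of its end at the lower coordinate. At its other end 4 CpGs were at 95.1% in TSPAN8-high (95% exact interval 90.2 to 98.0) and 96.2% in TSPAN8-low (90.4 to 98.9). Across the body of Tspan8, 43 CpGs were at 81.3% in TSPAN8-high, from 1129 reads, and 74.9% in TSPAN8-low, from 1192 reads, a difference of 6.39 percentage points (Fisher's exact test, p = 0.000205), which was 3.24 over 108 CpGs with 5 or more reads (Fisher's exact test, p = 0.00874) and 10.5 as a mean over cytosines with 10 or more. Id4, an inhibitor of basic helix-loop-helix factors and the gene behind the reporter (chromosome 13, 48261116 to 48266028), was unmethylated at its CpG-rich end, where 91 CpGs were at 1.61% in TSPAN8-high (95% exact interval 1.47 to 1.77) and 1.20% in TSPAN8-low (1.08 to 1.32). This difference of 0.414 percentage points had an adjusted p of 0.00407 (Fisher's exact test) and lay below the minimum of 10. The other end of Id4 was at 93.8% and 94.8%, and its body at 25.9% of pooled reads in TSPAN8-high and 29.1% in TSPAN8-low (Fisher's exact test, p = 2.02e-11). As a mean over cytosines the body of Id4 was at 26.5% and 26.4%, and over 23 bins of 100 bp the difference was -0.541 percentage points (95% interval -1.79 to 0.707). Reads over Id4 and 1 kb either side were deep, with a median of 105 in TSPAN8-high and 131 in TSPAN8-low against 11 in each library at 20 to 70 kb from the gene, and whether all reads behind the Id4 values come from the gene's own locus was not determined.

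The fifth comparison asked whether gene groups of spermatogonial development and of other testis cells differed, over 15 lists fixed before the data were examined. The only called member of any list was Hoxb3, a homeobox gene of the HoxB cluster, which was lower in TSPAN8-high (12.2% against 28.1%, adjusted p = 0.0223, Fisher's exact test). It was also the only member to pass adjusted over the list alone with the minimum of 10 percentage points. At any size of difference 9 members passed adjusted over the list alone and 7 over all promoters, and all of them but Hoxb3 differed by at most 3.94 percentage points. With 1 CpG kept per 100 bp none of these members passed over all promoters, but their differences did not all shrink. Hoxc8 went from -2.95 to -5.33 percentage points and Id4 from 0.414 to 0.770, while Tex15 went from 3.34 to 2.56 and Tet3 from -3.75 to -1.70. The thinned reads are part of those by which these members passed, so the kept differences are no independent support. Hoxb3 was called with windows of 500 bp, at 5 or more reads and at the less methylated gene end, but not with windows of 2 kb (4.27% against 7.59%) or with 1 CpG kept per 100 bp (a difference of -27.5 percentage points, adjusted p = 0.315, Fisher's exact test), and it was not measured at 20 or more reads. In those settings Insl3, Zfp57, Bmp4, Zfp42 and Msh5, each chosen after its values were seen, were called lower in at least 1. The other 37 measured Hox promoters were not called, with Hoxc11 at 5.25% in TSPAN8-high and 4.57% in TSPAN8-low and Hoxc13 at 0.676% and 0.608%. Of the stem cell and self-renewal genes, 26 were measured and 25 were below 20% in both libraries, among them Id4 and the transcription cofactor gene Taf4b (1.19% and 0.416%). All 14 measured genes of differentiating spermatogonia were below 20% in both, with the cyclin gene Ccnd2 at 1.38% and 1.88% and the DNA methyltransferase gene Dnmt3b at 0.272% and 0.566%. Of 25 measured meiosis genes 22 were below 20% in both libraries, with the chromosome axis gene Hormad1 at 0.733% and 0.713% and the synaptonemal complex gene Syce2 at 2.67% and 3.96%. Of 13 spermiogenesis genes 9 were below 20% in both, with the kinase gene Tssk3 at 0.563% and 0.717% and the glycolytic gene Gapdhs at 2.09% and 3.21%. Of 20 germline genes repressed by DNA methylation in somatic cells 17 were below 20% in both, with the RNA-binding protein gene Dazl at 2.95% and 2.04% and the mitochondrial carrier gene Slc25a31 at 2.08% and 2.91%. Among 21 pluripotency genes, Sall4 was at 2.91% and 1.65% and Klf2 at 0.926% and 0.222%. The median difference of that list, 0.516 percentage points, stood at the 98.1st percentile of 10000 random lists matched on methylation, the only list outside the central 95%. It stood outside as well with windows of 500 bp (98.0) and at the less methylated gene end (98.5), and inside at 20 or more reads (97.49), with windows of 2 kb (73.8) and at 5 or more reads (84.3). In other settings the Hox clusters (1.5 with windows of 2 kb and 1.66 at 20 or more reads) and the endothelial genes (2.43 at 5 or more reads) lay outside as well. With 15 lists compared, 1 list outside the central 95% would not be unusual by chance.

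None of the measured members of the remaining lists was called. Of 12 genes of DNA methylation and demethylation enzymes, 11 were below 20% in both libraries, with Mbd3 at 1.24% and 0.301% and Tet1 at 9.64% and 9.32%. All 26 TGF-beta, BMP and ID genes were below 20% in both, with Smad4 at 0.204% and 0.221%, and of 18 tetraspanins 16 were, with Tspan4 at 0.912% and 0.499% and Tspan18 at 1.86% and 0.742%. The cell type marker lists gave 13 Sertoli cell genes, with Sox9 at 0.873% and 1.12% and Clu at 0.586% and 0.156%, and 4 Leydig cell genes, with Nr2f2 at 1.35% and 1.13% and Pdgfra at 4.26% and 4.48%. They further gave 6 peritubular myoid cell genes, with Lmod1 at 2.40% and 2.76% and Tagln at 47.3% and 50%, and 5 endothelial genes, with Kdr at 1.02% and 0.645% and Sox17 at 0.816% and 0.256%. Of 5 macrophage and leukocyte genes, Cd14 was at 3.39% and 4.62% and Spi1 at 14.8% and 10.7%. Below 20% in both libraries were 12 of the Sertoli, 3 of the Leydig, 3 of the myoid and 4 of the endothelial genes. Of the macrophage and leukocyte genes 3 were. Above 80% in both were 1 myoid gene (Acta2), 1 endothelial gene (Erg) and 2 macrophage and leukocyte genes (Ptprc and Fcer1g). The other 14 lists lay between percentiles 14.9 and 77.0 of the random lists, which describe the lists and are not a test.

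**Figure D4:**
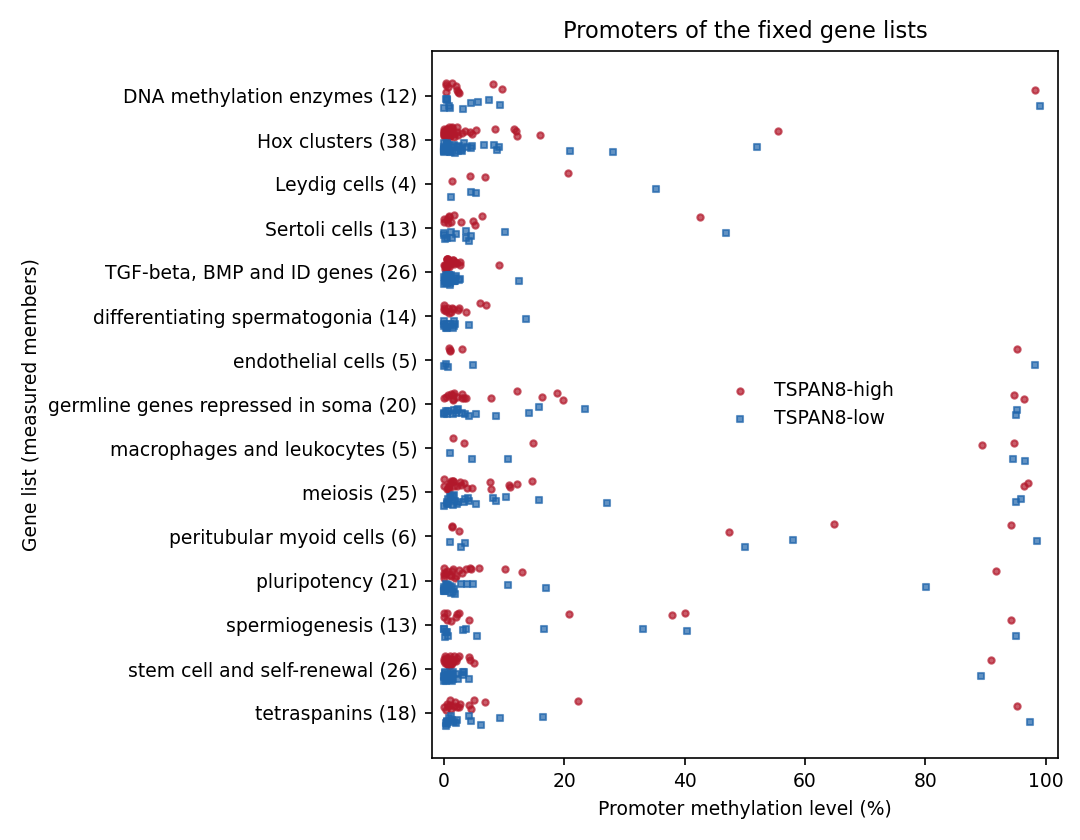
Promoter methylation level (percent) of every measured member of the 15 gene lists, with red circles for TSPAN8-high and blue squares for TSPAN8-low and the number measured in brackets. Most members lie below 20% in both libraries, and 1 member, Hoxb3, was called between them.

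The sixth comparison asked whether the imprinted regions had the methylation of male germ cells in both fractions, since regions methylated on the maternal copy lack methylation in the male germline and carry it on 1 of the 2 copies in somatic cells. The 12 measured regions methylated on the maternal copy had a median level of 2.03% in TSPAN8-high and 1.02% in TSPAN8-low, and 9 of them were below 5% in both libraries. These were the regions of Snurf (2.96% and 1.15%), of Peg3 and Usp29, which share a window (0.906% and 0.662%), of Kcnq1ot1 (0.412% and 2.42%), Airn (0.525% and 0.719%), Plagl1 (3.73% and 1.41%), Nnat (1.09% and 0.326%), Peg10 (0 of 222 reads, which allows up to 1.35%, and 0.337%), Peg13 (3.31% and 0.358%) and Zrsr1 (0.777% and 0.887%). Higher levels were found at Mest (17.7% and 17.3%), Mcts2 (20.2% and 27.1%) and Slc38a4 (14.6% and 15.3%). The regions methylated on the paternal copy were methylated in both fractions, at 98.1% and 96.1% upstream of H19, 96.1% and 98.2% upstream of Meg3 and 78.3% and 74.4% upstream of Rasgrf1. The opposite flanks were at 100% and 93.9% for H19, 96.4% and 100% for Meg3, each with 3 CpGs, and 37.0% and 31.0% for Rasgrf1. High levels upstream of H19 and Meg3 therefore cannot be told apart from those of their surroundings. Pooled over the 12 maternal regions the difference was -0.485 percentage points (95% interval -1.31 to 0.337). No region passed the adjusted threshold, and the lowest adjusted p was 0.0501 at Plagl1 (Fisher's exact test). Left out of these counts, by the promoter minimum of 5 CpGs, were 3 more methylated windows: Impact (96.0% and 98.3%, 4 CpGs), Snrpn (100% and 85.7%, 2 CpGs) and Nap1l5 (66.7% and 54.3%, 2 CpGs). At 5 or more reads 15 regions had at least 5 CpGs, with a pooled maternal difference of 0.286 percentage points, and at 20 or more 2 regions, with 0.182. Over the same 12 windows the pooled maternal difference was -0.546 percentage points at 5 or more reads (95% interval -1.24 to 0.147), and in the 8 with reads at 20 or more -1.22 (95% interval -3.03 to 0.555).

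**Figure D5:**
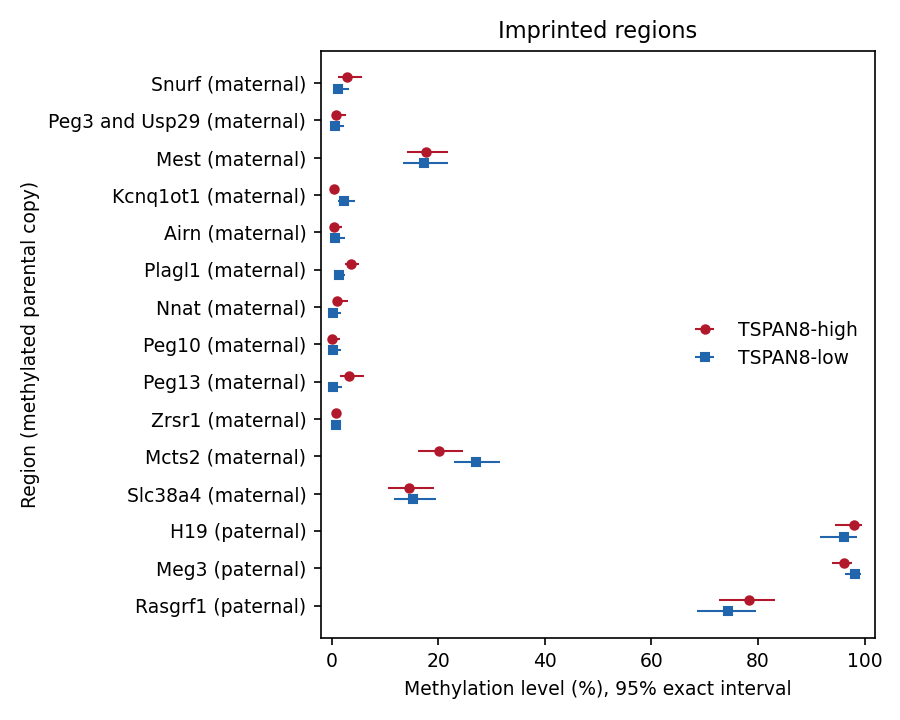
Methylation level (percent) of 15 imprinted regions in both libraries, with 95% exact binomial intervals as bars. The maternally methylated regions lie between 0 and 27.1% and the paternally methylated ones between 74.4% and 98.2%.

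The authors' deposited table classed 47277 cytosines as more methylated and 50714 as less methylated in TSPAN8-high, of 6745376 listed. In the authors' deposited table, classed cytosines had an unadjusted p of at most 0.05 and a difference in level of at least 0.1. After Benjamini-Hochberg adjustment over all listed cytosines, 95 of the cytosines classed in the authors' deposited table had an adjusted p below 0.05. With the same rule on 2256156 CpGs listed on both strands, the libraries differed at 40727 CpGs on the plus strand and 41173 on the minus strand, and the strands differed from each other at 44405 CpGs within TSPAN8-high and 43652 within TSPAN8-low.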

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

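Halved counts, merged strands, the less methylated gene end and the unchanged imprinted windows were chosen after seeing the data. The difference in overall level, averaged over cytosines, stayed negative, at -0.120 percentage points with at least 5 reads and -0.0836 with at least 20. Weighted by reads it was -0.578 with at least 10 reads, but 0.0345 with at least 20. At 5 reads the autosomes were at -0.120, gene ends at -0.0116, sites with 3 to 9 listed CpGs at -0.0784 and those with 10 or more at 0.0185. The Y chromosome was at -1.18 with 5 reads and -0.899 with 20. At 20 reads the autosomes were at -0.0832, gene bodies at -0.0719, intergenic sites at -0.132, sites with at most 2 listed CpGs at -0.121, with 3 to 9 at -0.0349 and with 10 or more at -0.0484. Single cytosines called numbered 75 at 5 reads, 284 with no minimum difference (98 higher and 186 lower), 71 without the deepest sites, 35 at equal coverage, 30 with halved counts and 236 with strands merged. Tiles called numbered 254 at 20 reads, 65 with 1 CpG per 100 bp, 597 with at least 20 percentage points and 317 with halved counts. Promoters called numbered 125 at 5 reads, 10 at 20 reads, 0 with 1 CpG per 100 bp, 18 with 500 bp, 170 with 2 kb, 399 with no minimum difference, 22 with the unweighted mean and 12 with halved counts. That counts rise with no minimum difference and fall with a higher one follows from the setting. The lean of single cytosines to lower levels with no minimum difference does not. The deep ribosomal DNA stretch described below, where 89.5% of 855 cytosines were lower in TSPAN8-high, gave no call at the minimum of 20 percentage points. How many of the added calls lie in that stretch was not counted, and the cause of the lean was not tested. For the other counts the cause was not tested either. Of the 48 promoters, 25 were called in the same direction at 5 reads, 2 at 20 reads, 9 with 500 bp, 23 with 2 kb, 20 with the unweighted mean, 11 with halved counts and 45 at the less methylated end. With 2 kb the direction turned at Cyp4a29 (-3.29), Rxfp2 (-1.03), Myo1h (1.92) and Rangrf (11.1), and with the unweighted mean at Ctc1 (-0.451), Pigu (-1.94), Schip1 (1.89) and Ddx47 (1.62), and the cause was not tested. Of the other values of named promoters 63 kept their call and 57 lost it, and 70 list medians kept within their interval and 4 left it. A lost call did not always go with a smaller difference. With halved counts Zscan26 was at 20.4 percentage points and Pgr at -21.4, while Trafd1 fell to 0.0397 with 2 kb. The pooled maternal imprinted difference was 0.286 over 15 regions at 5 reads and 0.182 over 2 at 20, but -0.546 and -1.22 over the unchanged windows, where the paternal one was -0.182 and -2.24, the last from 6 CpGs. At 20 reads the Leydig cell list gave no value, nor did the paternal regions with at least 5 CpGs. No paired analysis was possible because each fraction had 1 library.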

Other observations

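The tests on the calls between the libraries, the ribosomal DNA stretch and the depth over Id4 were chosen after the result was seen, while those on neighbours of single CpGs and on the chromosome 12 stretch were written down before. The unchanged imprinted windows were also set after. The rule that voided 1 test of each of these last was added after its result was seen, as was the interval of the depth on chromosome 12.

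The windows of 36 clustered protocadherin genes, which encode cell surface adhesion proteins, were 26 distinct ones, since 11 genes share an end, and 23 of these windows were not called. Over the 26 the median level was 5.48% in TSPAN8-high and 4.12% in TSPAN8-low. Pcdha3 was higher in TSPAN8-high (26.1% against 14.0%) and Pcdhac2 (6.63% against 19%) and Pcdhb3 lower. Pcdha3 and Pcdhac2 were chosen after their values were seen.

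A stretch of chromosome 17 annotated with the ribosomal RNA pseudogene Rn18s-rs5, which gathers reads of the many ribosomal DNA repeats, was less methylated in TSPAN8-high and was chosen after its values were seen. From 39843001 to 39848754 its 855 cytosines had a median of 482 reads in TSPAN8-high and 489 in TSPAN8-low, and pooled reads were methylated at 5.79% and 10%. Of these cytosines 89.5% were lower in TSPAN8-high, and the mean over 55 bins of 100 bp was -4.64 percentage points (95% interval -5.47 to -3.80).

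For this ribosomal DNA stretch, the strand nearer to 0 differed by -3.96 percentage points, with both strands below 0, which argues against noise confined to a strand. Sites with 10 or more listed CpGs in 200 bp differed by 0.000389 percentage points (95% jackknife interval -0.0344 to 0.0352), which argues against less complete bisulfite conversion in TSPAN8-low. More somatic cells in TSPAN8-low stay open. Pooled reads of the maternally methylated regions were higher there by 0.485 percentage points (95% interval -0.337 to 1.31). That is below the 2.26 that the smallest sufficient share of somatic cells would add, but that figure assumes how methylated those cells are. High minus low, the pooled difference of -0.485 became -0.546 over the same windows at 5 or more reads (95% interval -1.24 to 0.147). The regions did not move together: 6 were higher and 6 lower in TSPAN8-high, with the largest difference at Mcts2 (-6.84 percentage points). Their median was higher in TSPAN8-high (2.03% against 1.02%). A spread common to deeply read stretches also stays open, since 9.09% of 22 other deep windows of 10 kb, 2 windows with 39 cytosines each, had as low a difference. A difference between the fractions may therefore exist here, as a hypothesis, and cannot be told apart from a difference between libraries.

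Most calls of tiles and promoters may come from reads of 1 strand that are not independent, such as copied fragments or mates counted apart. After the libraries were exchanged on the minus strand, 80.6% as many tiles and 120% as many promoters were called as in the real comparison. The real comparison called 114 more tiles and, for promoters, a difference of -4, and whether the excess of tiles belongs to the fractions or to the libraries cannot be told apart, since each fraction had 1 library. With counts halved where all were even, 188 tiles and 7 promoters were called in the real comparison, against 124 and 6 after the exchange. Where the strands have unlike read numbers, part of a shared difference may remain among the exchanged calls.

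Single CpGs measured on both strands gave 332 calls in the real comparison and 72 after the exchange. With counts halved where all were even, these fell to 60 and 7, so the exchange gave 11.7% as many calls, which argues against repeated counting as the whole cause. CpGs beyond 150 bp and up to 1000 bp from a called CpG moved with it by 1.22 percentage points (95% interval -0.0755 to 2.52), which argues against a difference of 5 percentage points that far away. From 51 to 150 bp they moved with it by 3.9 percentage points (95% interval 0.586 to 7.22), against 2.24 (95% interval -4.44 to 8.91) after the exchange, so a shorter regional difference stays open. CpGs 2 to 50 bp away moved by 15 percentage points, which would have argued against a base variant, but they moved by 20.1 beside CpGs called after the exchange, where no variant is called, so that test decided nothing.

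Between 18000001 and 24000000 on chromosome 12, a stretch with many genes known by placeholder names, the difference was -1.80 percentage points (standard error 0.368), and 3 of 20 promoters were called, all lower in TSPAN8-high. The standard error takes no account of how the stretch was chosen. Among 2590 windows of 1 Mb, 1 on chromosome 13 and 1 on chromosome 5 lay further below 0 than any here (-4.31 and -4.29 standard errors, against -4.24). With the libraries exchanged on the minus strand, the highest window reached 4.91 standard errors. These were Gm10476 (10.1% against 51.3%, the largest difference of any called promoter at -41.2 percentage points), Gm40862 (37.4% against 66.4%) and Gm3993 (12.2% against 32.1%), chosen after their values were seen. The strand nearer to 0 differed by -1.62, which decided nothing because the stretch was chosen from both strands together. The median depth was 0.970 times that of the autosomes (95% bootstrap interval 0.939 to 1). This argues against reads of further near-identical copies gathered over most of the stretch. A median over 2558 cytosines cannot exclude such reads in parts of it. The window of 10 kb from 20220000 to 20229999 was among the 22 other deep ones. Its median reads were 31 in TSPAN8-high and 34.5 in TSPAN8-low, against 16 in each over the stretch. Reads placed at random among copies would leave the depth unchanged and were not tested.

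The depth over Id4 may come from extra copies of this stretch carried by the reporter transgene. Median reads over Id4 and 1 kb either side were 10.7 times those at 20 to 70 kb. Of the cytosines there 86.9% lay above 3 times the genome median, which argues against a few fragments copied in amplification. The deep stretch ran from 48255374 to 48267441 on chromosome 13 and had 1.23 times as many reads in TSPAN8-low as in TSPAN8-high. The methylation levels printed for Id4 may then be partly those of added copies. No biological explanation was tested, and a copy number difference of another origin was not tested either.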
